A study of Nicotiana attenuata with 6 samples.

How the data were processed

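RNA from leaves of *Nicotiana attenuata* was labelled with Cy3 and hybridised to single-colour Agilent arrays, 3 of wild type and 3 of the ir-lecRK1 line, 1 h after wounding plus oral secretions, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The design text of the series speaks of independent experiments for each genotype; whether an array held 1 plant or a pool is not given in the sources used here.

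The scanner files hold spot intensity. The scanning software was Agilent Feature Extraction 9.5, per the submitters' processing notes. The processed signal is an intensity after background subtraction and spatial and multiplicative detrending, per the file headers, and was not scaled between arrays. The mean signal and the local background are plain intensities, per the file headers, and flags mark spots well above background, saturated or not uniform. The series' value table, as deposited by the authors, is a linear ratio: for 5 of the 6 columns it equals the mean processed signal of a probe divided by the array's 75th percentile over all 45220 spots, with no centring of genes. This was found by setting each column against its scan, since no label states the step. The column of wild-type replicate 3 did not match its scan (r = 0.66), and its scale and origin stay unknown. Column medians were 0.0968, 0.0928 and 0.113 for wild type and 0.103, 0.0977 and 0.0894 for ir-lecRK1. The table was used only as an alternative, and every column was matched to a sample by its name.

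Control spots were left out, which kept 43803 spots for 43533 probes, and 1 to 26 spots per array flagged as outliers were removed. Saturation was flagged on 0 spots. Values were log2 of the processed signal minus the array's 75th percentile of it, averaged over spots of a probe. Probes well above background on at least 3 of the 6 arrays were tested, 25398 in all, of which 20985 carry a name and 4413 a contig identifier alone. Names are entries of the design's gene name column, mostly protein entries of other species, so a name marks similarity and not an established gene of this plant. No genome was used here and no table of genes was matched to the contigs. A probe that was well above background on none of a genotype's arrays has only a bound there, given as "at least N-fold": the brighter genotype's mean against the dimmer one's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

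Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment) in R 4.3.3, with all 6 arrays and no block. Gene lists were compared with camera of limma at a preset correlation of 0.01, with the brightest probe standing for a name with several probes and at least 5 measured names. Camera with an estimated correlation and fry were alternatives. Of 33 lists fixed in words, 28 could be tested. The lectin receptor kinase list had 3 measured names, salicylate 1, root markers 1, and trichome markers and selectable markers 0. The words of each list were turned into name patterns after the names on the array had been seen but before any difference between genotypes was computed. Design, lists and the rule for named genes were otherwise set before the data were examined, and so were the alternatives apart from the variance trend without robust estimates and the fits within the run of slides holding both genotypes.

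The rule took lectin receptor kinase probes past the threshold and any LecRK1 probe; the 12 named probes with the largest change in each direction among those past the threshold, or, with fewer than 5, the 8 with the smallest p, given as values; up to 4 members with the smallest p in each tested list; and a set of known anti-herbivore and jasmonate genes wherever named. Of the list members, the text names those of the lists that passed and a selection of the others, made after their values were seen. Lipoxygenase 3, isochorismate synthase, WRKY3, WRKY6, SIPK, WIPK, geranyllinalool synthase and hydroperoxide lyase were not named among the measured probes.

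The fit was tested on simulated data of 25353 probes with 200 changed. Means were those of the real probes, spreads were limma's moderated ones, and noise was independent between probes and arrays. The fit recovered 6 of 61 changes of 1 log2 unit, 60 of 69 of 2 units and 67 of 70 of 3 units. Of 144 calls, 11 were false. Real noise need not be independent, so these shares are not those of the real data. A list shifted by 0.5 log2 was recovered by camera and 0 other lists were called. That simulation held no variation shared by members of a list, while the real photosynthesis list had an estimated correlation of 0.58. It therefore cannot show how often camera calls lists whose members vary together.

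Alternatives covered background correction (normexp with an offset of 50, then quantile), quantile or median scaling, the value table, the filter on dim probes, a variance trend, array weights, a 2-fold minimum, an adjusted p of 0.1, a SAM-like d statistic, blocks for replicate number and run of slides, and each array left out. Slides fell into 2 runs of consecutive slide numbers: 4 arrays (1 wild type, 3 ir-lecRK1) and 2 arrays (wild type alone). The block and the fit within the first run therefore rest on the same contrast of 1 wild-type array with 3 ir-lecRK1 arrays, and the lone array is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9.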

Results

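Transcripts were measured in leaves of *Nicotiana attenuata*, a wild tobacco, in wild-type plants and in ir-lecRK1 plants, a line in which an inverted repeat silences lectin receptor kinase 1. Leaves were wounded, the wounds received 20 µL of diluted oral secretions of the specialist caterpillar *Manduca sexta*, and RNA was taken 1 h later. Each genotype was represented by 3 single-colour arrays, which the series text assigns to independent experiments. Each array carried 43533 probes, 1 per assembled transcript (contig), and 56.3% to 59.8% of them were well above background. The 75th percentile of signal was 171, 210 and 221 in wild-type replicates 1 to 3 and 155, 216 and 196 in ir-lecRK1 replicates 1 to 3. The number of arrays limits the precision: over 25398 probes kept for testing, the median standard error of a log2 difference was 0.24. Pearson's r across probes was 0.952 to 0.986 between arrays of one genotype and 0.957 to 0.984 between genotypes. Probe names below are those the array design gives, mostly protein entries of other species, and all log2 differences are ir-lecRK1 minus wild type.

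The first question was whether the silenced kinase itself was lower. The array design names no probe for LecRK1, so the genotype labels could not be checked on the target. Of the probes named for lectin or S-domain receptor kinases, 11 were measured, 7 of them higher and 4 lower in ir-lecRK1. Their differences ran from −0.46 to 0.28 with a median of 0.08 on the log2 scale, and 0 of them passed the adjusted threshold in limma. That median was 0.39 with the run of slides as a block and also within the run that held both genotypes, and −0.19 without wild-type replicate 1. With normexp background correction and quantile normalization it was −0.019, with 3 probes higher and 8 lower.

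The second question was which transcripts depended on LecRK1 after elicitation. The anti-herbivore list was fixed in words in advance. Its name patterns were written after the array's names had been seen but before any difference between genotypes was computed. Among the names of that list, the one with the smallest p was a threonine deaminase (THD1_SOLTU, contig Na_454_03285), the enzyme that opens isoleucine synthesis and also deprives caterpillars of dietary threonine. Its log2 signal relative to the 75th percentile was 2.09 ± 0.64 (SD, n = 3) in wild type and −0.20 ± 0.76 (SD, n = 3) in ir-lecRK1, a difference of −2.29 (SE 0.46), or 4.89-fold lower, with no overlap between genotypes. Its adjusted p was 1.00 over all probes, and 0.039 adjusted over the list alone, those 23 names. The list-alone adjustment was made in each of the 28 lists, with no correction over lists, and 1 list, this one, held a call. A further probe of the same name (Na_454_37775) differed by 0.16 (SE 0.27), and THD1_BURM1 by 0.51 (SE 0.23). THD1_PASMU was not well above background on the ir-lecRK1 arrays and was at least 1.26-fold lower there on the processed signal, with overlap between genotypes. Its log2 difference with normexp background correction and quantile normalization was −0.12, smaller than that bound. The offset of 50 added with normexp by itself shrinks differences of such dim probes.

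The transcript with the smallest p was Y5005_ARATH, at 2.47 ± 0.27 (SD, n = 3) in wild type and −0.61 ± 0.43 (SD, n = 3) in ir-lecRK1, a difference of −3.09 (SE 0.27) with an adjusted p of 0.13. SYVN1_MOUSE, named for an E3 ubiquitin ligase of the endoplasmic reticulum, was at 0.67 ± 0.06 (SD, n = 3) in wild type and 3.81 ± 0.82 (SD, n = 3) in ir-lecRK1, 8.84-fold higher, with an adjusted p of 0.32. The latex-type protein MLP43_ARATH was higher by 2.54 (SE 0.33) and RIN4_ARATH, named for a regulator of plant immunity, by 2.51 (SE 0.44). Differences were 2.09 for the alanyl-tRNA synthetase SYA_LEPBL, 1.92 for the lipid-transfer protein NLTPA_RICCO and 1.71 for a dihydroflavonol reductase (DFRA_HORVU, Na_454_23940). MUC7_HUMAN was higher by 1.29 and Y8484_DICDI by 1.14. On the lower side stood EIF3H_SCHPO, a translation initiation factor, at −1.21 (well above background on 2 of the 3 ir-lecRK1 arrays), the glycine-rich protein GRP1_DAUCA at −0.94 and the pentatricopeptide repeat protein PP427_ARATH at −0.91. Not well above background on any ir-lecRK1 array were PP227_ARATH, Y5370_ARATH and HUM6_CAEEL. On the processed signal they were at least 1.38-fold, 2.21-fold and 1.35-fold lower. Their log2 differences with normexp background correction and quantile normalization were −0.17, −0.27 and −0.15, smaller than those bounds. The normexp values include an added offset of 50, above the median processed signal of every array (15.7 to 20.9). That offset by itself shrinks the log2 differences of dim probes. With normexp background correction and quantile normalization, 12 of these 16 differences were smaller by over 1.5 times, among them 0.53 for SYA_LEPBL, 0.64 for NLTPA_RICCO, 0.55 for DFRA_HORVU, −0.20 for EIF3H_SCHPO, 1.49 for MLP43_ARATH and 1.30 for RIN4_ARATH, while Y5005_ARATH (−2.44), SYVN1_MOUSE (2.86), THD1_SOLTU (−1.94) and MUC7_HUMAN (1.18) moved less. In limma the smallest adjusted p of the 16 was 0.13, so no probe of these passed the threshold. Adjusted p was 0.32 for SYA_LEPBL, MLP43_ARATH and PP227_ARATH, 0.66 for DFRA_HORVU and 0.68 for NLTPA_RICCO. For RIN4_ARATH, MUC7_HUMAN, Y8484_DICDI, THD1_SOLTU, Y5370_ARATH, EIF3H_SCHPO, GRP1_DAUCA, PP427_ARATH and HUM6_CAEEL it was 0.99986. The 16 probes were the 8 named probes with the smallest p in each direction, so their lack of overlap between genotypes follows partly from how they were picked.

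**Figure D1:**
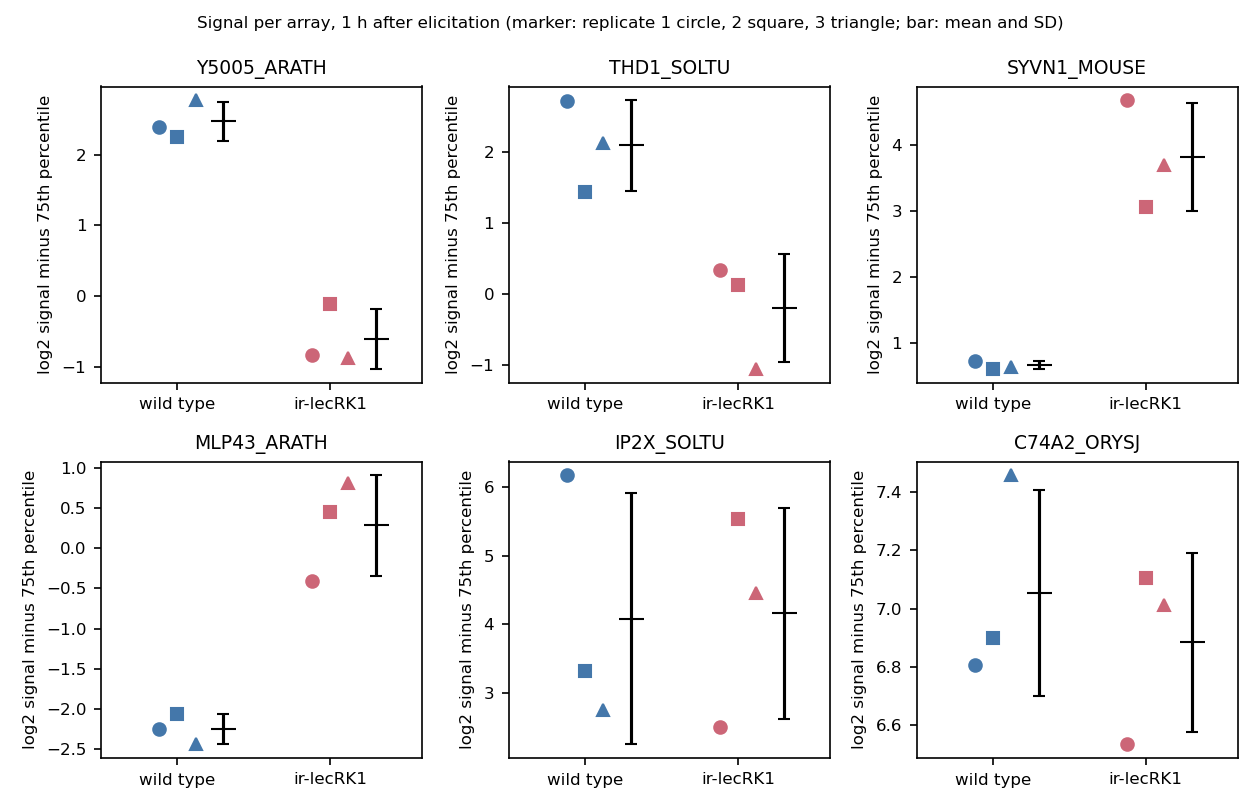
Log2 signal minus the array's 75th percentile for 6 named probes on each of the 3 wild-type and 3 ir-lecRK1 arrays, with markers for replicates and a bar for the mean and SD; each panel has its own scale. Y5005_ARATH and THD1_SOLTU lay lower on all 3 ir-lecRK1 arrays, SYVN1_MOUSE and MLP43_ARATH lay higher, while the proteinase inhibitor IP2X_SOLTU (4.08 ± 1.83 and 4.16 ± 1.54, SD, n = 3) and allene oxide synthase C74A2_ORYSJ overlapped between genotypes.

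Across all 25398 probes, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 529, against 1270 that chance would give. Of these, 277 were higher and 252 lower, and 113 differed at least 2-fold (64 higher, 49 lower). The balance depended on the scaling: 246 higher and 280 lower with quantile normalization, 198 and 294 with a median shift, but 241 and 199 with normexp. A SAM-like d statistic also called 0. With the 6 arrays' values fully separated by genotype there were 1390 probes, 5.48% of those tested, where chance gives 10%. The run of slides, which put wild-type replicate 1 with the 3 ir-lecRK1 arrays, left the call at 0 as a block (1493 at an unadjusted p under 0.05) and within the run holding both genotypes (1826). Both fits set wild-type replicate 1 alone against the 3 ir-lecRK1 arrays, since the other run held wild type alone, and gave −2.91 for THD1_SOLTU, −3.01 for Y5005_ARATH and 3.07 for SYVN1_MOUSE. The series text gives 148 differentially regulated genes without a criterion.

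Of other jasmonate-linked transcripts, 0 passed the threshold over all probes. Allene oxide synthase (C74A2_ORYSJ, Na_454_00189), an early enzyme of jasmonate synthesis, differed by −0.17 (SE 0.26), and 0.08 within the run holding both genotypes. The jasmonate methyltransferase name JMT_BRARP differed by −0.96 (SE 0.34). Over the 10 jasmonate biosynthesis names the median was 0.08 but the mean −0.01 and the direction of the test was down (adjusted p = 0.83). The jasmonate signalling list had 8 of 11 names higher, with a median of 0.11 (adjusted p = 0.66). Among anti-herbivore names 16 of 23 were higher, with a median of 0.07, a mean of −0.02 and a downward test (adjusted p = 0.90). Within the run holding both genotypes that median was −0.59 (adjusted p = 0.0047), resting on a single wild-type array, and without ir-lecRK1 replicate 1 it passed in the opposite direction at 0.36 (adjusted p = 0.034). The proteinase inhibitor IP23_CAPAN differed by 0.77 (SE 0.27) and IP2X_SOLTU (Na_454_02256) by 0.07 (SE 1.06), but by −2.02 within that run. Putrescine N-methyltransferase (PMT4_TOBAC), which commits putrescine to nicotine, differed by 0.22 (SE 0.32), and by −0.38 within that run. The nicotine and polyamine list had a median of −0.06 (adjusted p = 0.83), and −0.32 within that run (adjusted p = 0.0093). Its member with the smallest p, PAOX_ARTGO, carries a bacterial amine oxidase name and differed by 0.85 (SE 0.19). NPR1_ARATH, a salicylate receptor, differed by 0.27 (SE 0.19) and was the 1 measured name of the salicylate list.

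2 of the 28 gene lists tested passed an adjusted p of 0.05 by camera with a preset correlation of 0.01, and 0 passed with an estimated correlation or by fry. The NAC transcription factors, regulators of stress and senescence programmes, passed on the higher side in ir-lecRK1. Of 20 names 16 were higher, with a median of 0.18 (camera adjusted p = 0.0054, and 0.57 with an estimated correlation). That estimate was 0.017, near the preset, and the camera p with it was 0.028 before adjustment over the lists. NAC66_ARATH differed by 0.55 (SE 0.19), NAC29_ARATH by 0.59 (SE 0.21), NAC71_ORYSJ by 0.43 (SE 0.20) and NAC72_ARATH, well above background on 2 of the 3 wild-type arrays, by 0.96 (SE 0.54). The photosynthesis list also passed on the higher side, with 44 of 50 names higher and a median of 0.22. Its camera adjusted p was 0.0054, and 0.97 with an estimated correlation, which was 0.58. The large subunit of Rubisco (RBL_NICTO) differed by 0.53 (SE 0.21), the light-harvesting protein CB22_TOBAC by 0.44 (SE 0.34), Rubisco activase (RCAA_HORVU) by 0.28 (SE 0.22) and the thylakoid protein TL14_SPIOL by 0.27 (SE 0.20). Of single members, 0 passed over all probes in any list. With the run of slides as a block, and equally within the run holding both genotypes, the photosynthesis median was −0.41, a contrast that rests on wild-type replicate 1 alone, and the NAC median was 0.29 (adjusted p = 0.088) as a block and 0.25 (adjusted p = 0.27) within that run. With normexp and quantile scaling the NAC and photosynthesis medians were 0.097 and 0.13, and with the value table of the series 1.01 and −0.36. The photosynthesis median was 0.56 without wild-type replicate 1 and −0.05 without wild-type replicate 3. Without wild-type replicate 2 it was 0.18, with 42 of 50 names higher and a camera adjusted p of 0.43. The NAC call was lost (medians 0.12 to 0.17) without wild-type replicate 1, wild-type replicate 2 or ir-lecRK1 replicate 3 (adjusted p = 0.14, 0.22 and 0.21).

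**Figure D2:**
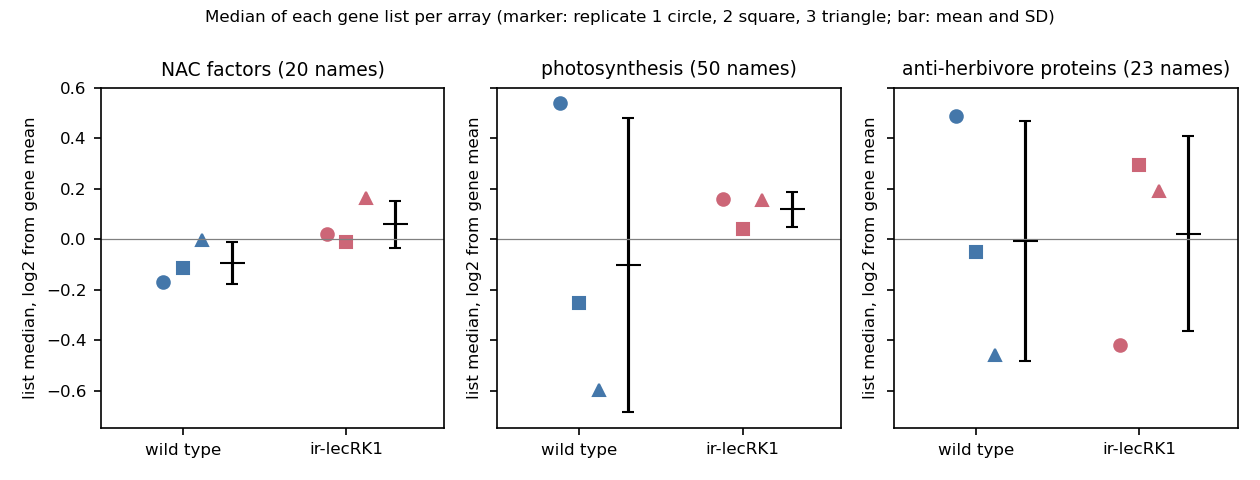
Median over the names of 3 gene lists on each of the 3 wild-type and 3 ir-lecRK1 arrays, in log2 units from each gene's mean over all 6 arrays, with markers for replicates and a bar for the mean and SD. For photosynthesis the wild-type arrays lay at 0.54, −0.25 and −0.60 around ir-lecRK1 values of 0.04 to 0.16, and the medians of the anti-herbivore list and of the NAC list (−0.17 to −0.0037 in wild type, −0.011 to 0.16 in ir-lecRK1) overlapped between genotypes.

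The other 26 lists had adjusted p from 0.13 to 0.90. Calls below with an array left out or within a run used camera at the preset correlation of 0.01. Over all 6 arrays the estimated correlation was 0.27 for terpenoids, 0.14 for WRKY, 0.13 for pathogenesis-related proteins and 0.11 for cell wall. For clock genes, phenylpropanoids and MYB it was 0.08, 0.07 and 0.04. For green leaf volatiles, AP2/ERF, ethylene and conjugating enzymes it was −0.019 to 0.020. Where members vary together, such adjusted p are too small. Other transcription factor lists had most names higher in ir-lecRK1 without passing. These were AP2/ERF with 33 of 49 (median 0.16, adjusted p = 0.13), MYB with 15 of 17 (0.10, adjusted p = 0.27) and WRKY with 22 of 35 (0.07, adjusted p = 0.44). EF112_ARATH differed by 0.74 (well above background on 2 of the 3 wild-type arrays) and MYB05_ANTMA by 0.66. List medians per array separated by genotype for AP2/ERF. For MYB the lowest of the 6 was ir-lecRK1 replicate 1 (−0.24), and for WRKY the highest was wild-type replicate 3 (0.22). The WRKY median was 0.28 within the run holding both genotypes (adjusted p = 0.0093) and 0.20 without wild-type replicate 3 (adjusted p = 0.0055). AP2/ERF also passed without wild-type replicate 3 (median 0.15, adjusted p = 0.039) and with all probes of a name kept, and MYB without ir-lecRK1 replicate 1 (0.25, adjusted p = 0.0055). Of hormone and volatile lists, ethylene had a median of 0.10 (adjusted p = 0.27), green leaf volatiles 0.11 (0.29), abscisate and dehydration 0.04 (0.76), and auxin, gibberellin and cytokinin 0.03 (0.74). Without ir-lecRK1 replicate 1 the ethylene list passed at 0.22 (adjusted p = 0.028) and green leaf volatiles at 0.20 (adjusted p = 0.034). In secondary metabolism, 29 of 43 phenylpropanoid names were higher (median 0.10, adjusted p = 0.38). Another DFRA_HORVU probe (Na_454_02776) differed by 0.96 and the flavonoid 3'-hydroxylase name F3PH_ARATH by −0.87. Terpenoid names had a median of −0.11 (adjusted p = 0.57) and conjugating enzymes with cytochromes P450 0.11 (adjusted p = 0.29). Leaving out ir-lecRK1 replicate 1 brought the phenylpropanoid list to 0.25 (adjusted p = 0.0055) and the conjugating enzymes to 0.17 (adjusted p = 0.0047), and leaving out ir-lecRK1 replicate 2 brought the terpenoid list to −0.23 (adjusted p = 0.022). In signalling and immunity, kinases of the MAPK and calcium type had a median of 0.01 (adjusted p = 0.83), receptor-like kinases 0.05 (0.87), resistance proteins 0.05 (0.82), pathogenesis-related proteins 0.06 (0.74) and redox proteins 0.06 (0.68); the pathogenesis-related list passed at 0.20 without ir-lecRK1 replicate 1 (adjusted p = 0.0046). Growth-related lists had medians of −0.01 for ribosomal proteins (adjusted p = 0.87), 0.02 for cell wall (0.68) and 0.01 for histones and cell cycle (0.83). The cell wall median was −0.23 within the run holding both genotypes (adjusted p = 0.00027), and −0.07 without wild-type replicate 3 (adjusted p = 0.033). Signs of handling and harvest time did not pass with all 6 arrays: heat shock proteins had a median of −0.12 (adjusted p = 0.38), and clock genes 0.02 with a mean of −0.09 and a downward test (adjusted p = 0.44). Without ir-lecRK1 replicate 1 the clock list passed on the lower side at −0.17 (adjusted p = 0.032). Clock members with the smallest p were ELF3_ARATH at −1.49 (SE 0.51; well above background on 1 of the 3 ir-lecRK1 arrays), COL10_ARATH at −0.71 and ADO1_ARATH at −0.79. Vascular markers had a median of 0.05 and virus and transposon names 0.06 (adjusted p = 0.90 for both). The signs of median, mean and test differed in 6 lists, the 3 named above as going down by the test and also MAPK and calcium kinases, ribosomal proteins and cell wall.

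The deposited value table did not match the scan of wild-type replicate 3. The array values above come from the scans, except where the value table of the series is named. Without that replicate limma called 0 probes, 769 reached an unadjusted p under 0.05, and 4 lists passed.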

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

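The fit with a variance trend but without robust estimates, and all fits within the run of slides holding both genotypes, were chosen after the data were seen. Limma's count of 0 probes held under each alternative except array weights (1 probe, the unnamed contig Na_454_31426, higher) and the variance trend without robust estimates (1 probe, Y5005_ARATH, lower, adjusted p = 0.049). The smallest adjusted p ranged from 0.046 to 0.80 over the alternatives. At an unadjusted p under 0.05 the count ranged from 377 to 1849, with 1849 for array weights, 1826 within the run, 1493 for the run as a block, 1419 without the filter on dim probes, and 377 to 1256 with an array left out (1256 without wild-type replicate 1). Without the filter the median of all probes moved to 0.10. At least 2-fold, the count ranged from 15 (normexp) to 823 (within the run). A fit with the replicate number as a block called 0 probes and 2 lists; deviations of same-numbered arrays correlated at −0.29 to 0.13, and 1 of 6 arrays correlated best with its own number, so the numbers were not read as pairs. In simulated data with this number of arrays and independent noise, 6 of 61 changes of 1 log2 unit and 60 of 69 of 2 units were recovered. Differences of probes near background shrank with normexp. Its added offset of 50 brings this about by itself, so neither the shrinkage nor the low normexp count at least 2-fold is a check of those differences.

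The count of lists was 12 with the value table (9 higher, 3 lower), 0 without the filter, with an estimated correlation and by fry, 5 with the run as a block and within the run (anti-herbivore, nicotine and polyamine, cell wall and photosynthesis lower and WRKY higher, against a single wild-type array), and 0 to 10 with an array left out. Without ir-lecRK1 replicate 1 the 10 were NAC, MYB, photosynthesis, phenylpropanoid, ethylene, green leaf volatiles, pathogenesis-related, conjugating enzymes and anti-herbivore higher, the last opposite to its call within the run, and circadian clock lower. Without wild-type replicate 3 the 4 were NAC, WRKY and AP2/ERF higher and cell wall lower, and terpenoids were lower without ir-lecRK1 replicate 2. Calls with an array left out or by run all used the preset correlation of 0.01, with no estimate from those arrays. The NAC list passed with a median of 1.01 with the value table and 0.097 with normexp. Its median was 0.19 without the filter (adjusted p = 0.48), 0.29 with the run as a block, 0.25 within the run, 0.18 with an estimated correlation and by fry (adjusted p = 0.57 and 0.25), and 0.12 to 0.21 with an array left out; the call was lost in these apart from 3 of the left-out arrays, and the adjusted p ranged from 0.0038 to 0.57. The photosynthesis median was −0.36 with the value table, 0.13 with normexp, −0.41 with the run as a block and within the run, 0.22 without the filter, with an estimated correlation and by fry (adjusted p = 0.48, 0.97 and 0.99), and −0.052 (without wild-type replicate 3) to 0.56 with an array left out. The median of the lectin receptor kinase probes was 1.102 with the value table and −0.019 with normexp. It was 0.39 with the run as a block and within the run, and −0.19 to 0.18 with an array left out.

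Of 766 values of 43 named genes under the alternatives, 43 had the opposite sign, 15 of them with an array left out, and 1 passed the threshold. With the value table, of the 16 leading differences 4 were smaller and 2 larger by over 1.5 times, and the sign turned for C74A2_ORYSJ (3.31), IP2X_SOLTU (−1.21), ITH5_CUCMA (−0.97), ICI1_SOLLC (−0.91), PMT4_TOBAC (−0.37), Y8484_DICDI (−0.23), THD1_SOLTU Na_454_37775 (−0.18), RCAA_HORVU (−0.11), THD1_BURM1 (−0.024), and, within 0.01 of 0, TL14_SPIOL (−0.0078), NAC72_ARATH (−0.0052) and RBL_NICTO (−0.0017). With the run as a block, and equally within the run, it turned for IP2X_SOLTU (−2.02), ITH5_CUCMA (−1.96), ICI1_SOLLC (−1.81), PMT4_TOBAC (−0.38), CB22_TOBAC (−0.35), RCAA_HORVU (−0.12) and C74A2_ORYSJ (0.079). C74A2_ORYSJ was at 0.018 with array weights and ITH5_CUCMA at −0.00045 with a median shift. With an array left out, values ran from −0.30 to 0.032 for C74A2_ORYSJ, −0.11 to 0.51 for PMT4_TOBAC, −0.027 to 0.36 for THD1_SOLTU Na_454_37775, −0.48 to 1.104 for ICI1_SOLLC, −0.57 to 1.04 for ITH5_CUCMA and −0.61 to 1.12 for IP2X_SOLTU. The cause was not tested for these, apart from the tests given under the other observations.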

Other observations

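The tests on the value table's scaling and row order, on the spread of anti-herbivore transcripts, and on the photosynthesis list by run of slides, all values within the run holding both genotypes, and the counts of probes over the splits were chosen after the result was seen. Anti-herbivore transcripts spread widely over the 6 arrays. Over the 23 measured names the median range was 1.27 log2 units, against 0.77 over all 17745 names, and 7 of the 23 (30.4%) ranged over more than 2 log2 units, against 6.06% of all names. THD1_SOLTU had the widest range, 3.77, and separated by genotype. The next in range, the polyphenol oxidase PPOE_SOLLC and the proteinase inhibitors IP2X_SOLTU, ITH5_CUCMA and ICI1_SOLLC, did not. IP2X_SOLTU stood at 6.18, 3.32 and 2.75 on wild-type replicates 1 to 3 and at 2.50, 5.53 and 4.45 on ir-lecRK1 replicates 1 to 3, a range of 12.8-fold with a difference of 0.07 between genotype means. Scaling between arrays is argued against as the whole cause, since quantile normalization kept a median of 97.5% of the members' ranges, and so is the run of slides, since the 4 arrays of the run holding both genotypes spanned a median of 94.6%. Differences between experiments in how far these genes were induced at 1 h may account for it, a hypothesis with no test in this design.

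The 2 list calls were set against the 10 splits of the 6 arrays into 3 and 3. The photosynthesis list passed in 7 splits, so members varying together between arrays whatever the genotype may account for its call. Within the run holding both genotypes its median was −0.41, but against 1 wild-type array, so a difference between runs cannot be told apart from that array's own level. The NAC list passed in 1 split, the real one. Since it was picked for passing there, 1 is the lowest count possible and 10 splits are too few to exclude shared variation for it. The estimated correlation of its members was 0.017, against 0.58 for photosynthesis. Within the run the NAC median was 0.25, against 0.18 with all 6 arrays, but it rests on 1 wild-type array. The run of slides therefore cannot be excluded for it, and a genotype effect stays open.

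For all counts the 10 splits are too few for a share under 0.05. For probes past the adjusted threshold the real count was 0, so no split could give fewer and the comparison decides nothing. The highest other count was 1. For probes at an unadjusted p under 0.05, 8 splits gave at least the real 529, with a highest other count of 3002 for wild-type replicates 1 and 2 with ir-lecRK1 replicate 1 against the rest. For lists 9 splits gave at least the real 2, with a highest other count of 10. Splits that call several times the real count point to a structure of the samples other than genotype. Wild-type replicate 3 stood apart on the first principal component (38.7% of the variance), at 77.7 against −46.7 to 5.88 for the others.

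The value table's column for wild-type replicate 3 departed from its scan, while the other 5 columns equalled theirs. Relative to the scan the column was lower by over 4-fold for 13.2% of 17745 names and higher by over 4-fold for 8.93%. By list, the median column minus scan was −4.999 for WRKY factors (25 of 35 names lower by over 4-fold), −2.74 for jasmonate signalling, −2.12 for NAC factors and −2.03 for jasmonate biosynthesis, and 1.45 for photosynthesis. Another scaling of the same scan is argued against by a Spearman's rho of 0.70, and a complete shuffle of probe rows by a Pearson's r of 0.66. Rows out of order in part could leave such an r and were not tested. Pairs of probes with one name shared their column-minus-scan difference (r = 0.34 over 3296 pairs, against −0.01 when shuffled). The column may hold values of another hybridisation, but this does not single that out. The difference contains the scan's own level, which probes of one name can share, and shuffling breaks only the pairing by name. Over the scans of all arrays, Pearson's r with the column ran from 0.66, for its own scan, to 0.77. No biological explanation was tested, and which sample the column holds cannot be read from the values.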
